A study of Mus musculus with 12 samples.

How the data were processed

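The data are RNA-seq gene counts of 12 adipose tissue libraries from male C57BL/6J mice. Per the labels, the mice were 6 to 10 weeks old, ate a standard low-fat diet, and the tissues had been surgically denervated. The 4 depots were interscapular brown adipose tissue (BAT) and epididymal, inguinal and retroperitoneal white adipose tissue (EWAT, IWAT and RWAT), with 3 libraries each. No innervated tissue was analysed here, so an effect of denervation cannot be measured, and depot is the only factor. The labels do not say that the 3 libraries of a depot came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

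Per the labels' protocols, ribosomal RNA was depleted from total RNA, and libraries were sequenced as single-end 75-base reads. Per the submitters' processing notes, the authors used Trimmomatic 0.36, RSEM 1.3.0 and DESeq2 1.10.1 with genome build GRCm38.p4; the annotation, and whether reads were counted by strand, are not given in the sources used here. The deposited values are RSEM estimated counts per gene (expected counts, not normalised), with the TPM computed by the authors and, per the file headers, a posterior standard deviation of each count. TPM values were not used for any test. The files hold 47729 genes, of which 47224 gene identifiers matched the GENCODE M21 annotation of GRCm38 used here for symbols and coordinates. A symbol shared by several identifiers occurred 136 times.

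Estimated counts were rounded to whole numbers. Genes with too few counts were removed with filterByExpr, which left 19154 genes, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in 1 fit of all 12 libraries with 1 coefficient per depot. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 3 main comparisons were BAT against the mean of the 3 white depots, IWAT against the mean of EWAT and RWAT, and EWAT against RWAT; the other pairs of depots followed. A gene was taken as enriched in a depot when it was called, with a log2 fold change of at least 1, against each of the 3 other depots. Levels are TMM-scaled CPM, given as mean ± SD. The mean of several depots in a comparison is the mean of their fitted log2 levels. A depot near 0 therefore weighs heavily on the fold change. Fitted fold changes of genes near 0 in a depot also depend on the prior count that edgeR adds, so their levels are given too.

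There were 32 fixed gene lists, of adipocyte programmes, developmental genes and cell type markers. The 30 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. Adjusted p-values with a correlation estimated from the data, and from fry, are alternatives. Beside the calls over all genes, the text gives the number of members called when adjusted over the list alone. The samples, tests, lists and most alternatives were fixed before the data were examined.

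The genes named in the text follow a rule. It takes a set of core genes per main comparison, whatever their values, and the 5 largest changes in each direction among called genes. The latter need a mean log2 CPM of at least 3 and depots whose libraries do not overlap, and unnamed or predicted genes are left out. From each list chosen for a comparison it takes the called members with the 2 largest changes in each direction or, with none called, the member with the highest mean. For enriched genes it takes the 5 largest under the same limits. Genes outside the rule are named with a statement that they were chosen after their values were seen.

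Library totals ran from 15699912 to 25633413 counts. A count of 0 allows a level of up to 3 counts, which is 0.191 CPM in the smallest library; this floor covers counting error only. No 2 libraries held identical values, and no 2 of the same depot agreed within sampling noise.

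Each test was tried on simulated data with known answers, in which 200 genes were changed by fixed folds. For BAT against white (18785 genes) the test recovered 8% of genes changed 2-fold, 50% at 4-fold, 84% at 8-fold and 86% at 16-fold, with 7 false calls among 121. For IWAT against EWAT and RWAT (18793 genes) it recovered 10%, 62%, 80% and 86%, with 6 false calls among 126. For EWAT against RWAT (18756 genes) it recovered 0%, 48%, 70% and 96%, with 7 false calls among 114. In 8 simulations with no change, these 3 comparisons gave 0 calls each. When the thermogenic list was changed 2-fold, camera called 1 of 30 lists, that list, at an adjusted p of 1.67e-08. All these simulations drew each gene independently, without correlation between genes. In the data the estimated correlation of this list was 0.627, so the simulations do not show how the tests behave there.

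The alternatives fixed at the outset were DESeq2 1.42.0, limma-voom, RLE scaling, library sizes without TMM, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, glmTreat against a 1.5-fold change, a fit of only the depots compared, leaving out genes of mitochondrial, ribosomal and small RNA, and leaving out each library in turn. After the data were seen, 3 were added: 1 surrogate variable (sva 3.50.0), voom with sample quality weights, and leaving out 5740 genes whose posterior SD exceeds 1% of the count.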

Results

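The 12 libraries of denervated fat held between 15699912 and 25633413 counts, and 3.28% to 19.0% of the counts of a library came from the mitochondrial genome. Across genes, which are not independent replicates, Pearson's r was 0.882 to 0.973 between libraries of the same depot and 0.80 to 0.967 between libraries of different depots. The biological coefficient of variation was 0.448. The first principal component held 47.8% of the variance and the second 13.6%. Libraries of the same depot differed widely in their adipocyte and immune genes. In BAT, the mean log2 CPM of the de novo lipogenesis list was 10.37, 9.63 and 8.32 in replicates 1 to 3, and that of the macrophage markers 5.19, 5.63 and 7.72. In RWAT, the lipogenesis list had means of 9.47, 6.06 and 6.28 and the macrophage markers 6.13, 7.73 and 7.58. The EWAT libraries lay closer together, with 6.99, 6.82 and 6.18 for lipogenesis and 7.83, 8.23 and 8.29 for macrophage markers.

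**Figure D1:**
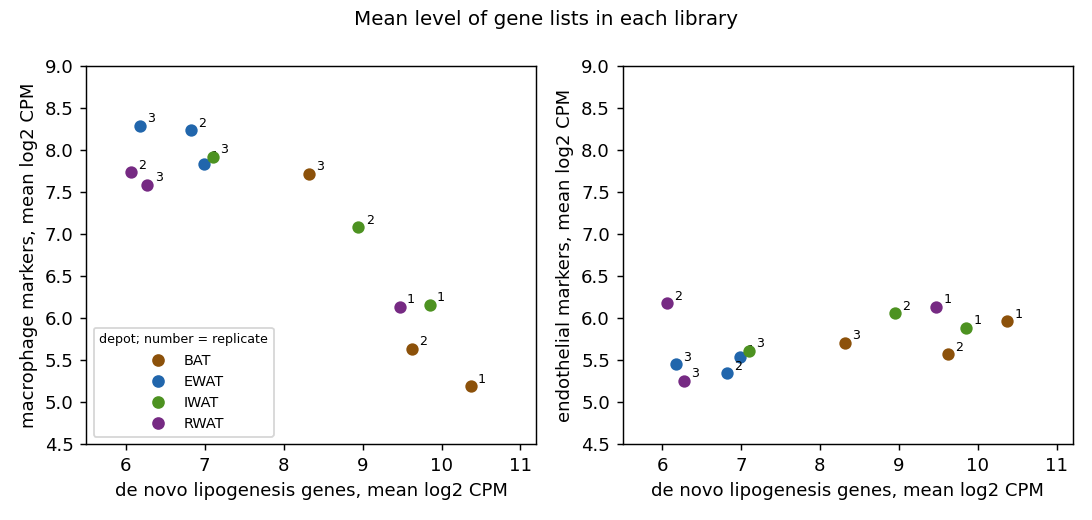
Mean log2 CPM of the macrophage markers (left) and of the endothelial markers (right) against that of the de novo lipogenesis genes; each point is a library, coloured by depot and numbered by replicate. Macrophage markers ran from 5.19 in BAT replicate 1 to 8.29 in EWAT replicate 3.

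Between denervated BAT and the mean of the 3 white depots, edgeR called several genes of the brown adipocyte programme, and none of these was called between BAT and IWAT alone. Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452 on GRCm38), the uncoupling protein of brown fat, averaged 1232 ± 1535 CPM in BAT (n = 3), 66.3 ± 56.5 in IWAT, 4.62 ± 6.75 in RWAT and 0.0452 ± 0.043 in EWAT, where it was under the floor. Its log2 fold change in BAT against the white mean was 8.92 (SE 1.25, adjusted p = 0.0356). That mean is of log2 levels, which the EWAT value near 0 lowers. The 3 BAT libraries held 2962, 32.2 and 702 CPM of Ucp1. The second of these lay below IWAT replicates 1 and 2, with 47.6 and 130 CPM of Ucp1. Lhx8 (chromosome 3, 154306294 to 154330659), a homeobox gene of brown preadipocytes, rose by a log2 fold change of 4.92 (SE 0.39, adjusted p = 0.00185). It averaged 10.5 ± 4.23 CPM in BAT, 3.35 ± 1.03 in IWAT and 0.0452 ± 0.043 in EWAT, under the floor. All 3 BAT libraries lay above all 9 white ones, and Lhx8 was called under all 24 alternatives (adjusted p up to 0.0169). Cox7a1, a subunit of cytochrome c oxidase found in muscle and brown fat, rose by 4.91 (SE 0.69, adjusted p = 0.0356) to 148 ± 178 CPM. Slc27a2, a very long chain acyl-CoA synthetase, rose by 6.62 (SE 0.82, adjusted p = 0.0272) to 45.5 ± 49.4 CPM. It held 0.153 ± 0.102 CPM in EWAT and 0.164 ± 0.0741 in RWAT, both under the floor. Elovl3, a fatty acid elongase, rose by 6.32 (SE 0.95, adjusted p = 0.0482) to 30.1 ± 40 CPM, against 0.0452 ± 0.043 in EWAT, under the floor. Cpn2, a carboxypeptidase N subunit, rose by 5.72 (SE 0.80, adjusted p = 0.0356) to 15.5 ± 16.3 CPM. It held 0.0604 ± 0.0646 CPM in EWAT and 0.164 ± 0.18 in RWAT, both under the floor. The signalling adaptor Traf4 rose by 1.44 (SE 0.21, adjusted p = 0.0411). Hoxc10, a posterior homeobox gene, changed by −6.66 (SE 0.99, adjusted p = 0.0437). Its level was 0.0262 ± 0.0454 CPM in BAT, under the floor, against 8.72 ± 2.44 in IWAT, 4.82 ± 3.18 in RWAT and 0.534 ± 0.281 in EWAT.

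Other genes tied to brown fat did not pass the test. Dio2, which activates thyroid hormone, held 57.8 ± 57.5 CPM in BAT and 12.6 ± 10.4 in IWAT (log2 3.76, adjusted p = 0.092). Cidea, a lipid droplet protein, held 380 ± 419 CPM in BAT and 77.5 ± 57.8 in IWAT (log2 5.22, adjusted p = 0.122). Ppargc1a, a coactivator of mitochondrial genes, had a log2 fold change of 2.43 (adjusted p = 0.092), Zic1, a marker of interscapular brown fat, of 4.62 (adjusted p = 0.0554), and Prdm16, a brown fat regulator, of 1.29 (adjusted p = 0.145). Zic1 held 6.09 ± 6.28 CPM in BAT and 0.0938 ± 0.0382 in EWAT, under the floor. DESeq2 called these 5 genes, with adjusted p = 0.000535 for Dio2, 0.0272 for Cidea, 0.00164 for Ppargc1a, 2.08e-05 for Zic1 and 0.0449 for Prdm16, the lowest of 23 or 24 alternatives, which ranged up to 0.693, 0.866, 0.617, 0.189 and 0.885. With 1 library left out, edgeR called Cidea, Ppargc1a and Zic1 without RWAT replicate 1 (adjusted p = 0.0461 each) and Zic1 without RWAT replicate 3 (adjusted p = 0.0024). Zic1 was also called with RLE normalization (adjusted p = 0.0499) and without a low-count filter (adjusted p = 0.0315), among others. The fit with the replicate number as a block, given below, called Cidea, Ppargc1a, Prdm16 and Zic1 but not Dio2. The β3-adrenergic receptor gene Adrb3 held 208 ± 137 CPM in BAT and 131 ± 82.1 in IWAT (log2 1.45, adjusted p = 0.331). The adipokine genes Lep (log2 0.03, adjusted p = 0.988) and Adipoq (log2 0.83, adjusted p = 0.412) did not pass either. Th, which encodes the enzyme that starts noradrenaline synthesis, had 7 counts over the 12 libraries and was not tested.

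**Figure D2:**
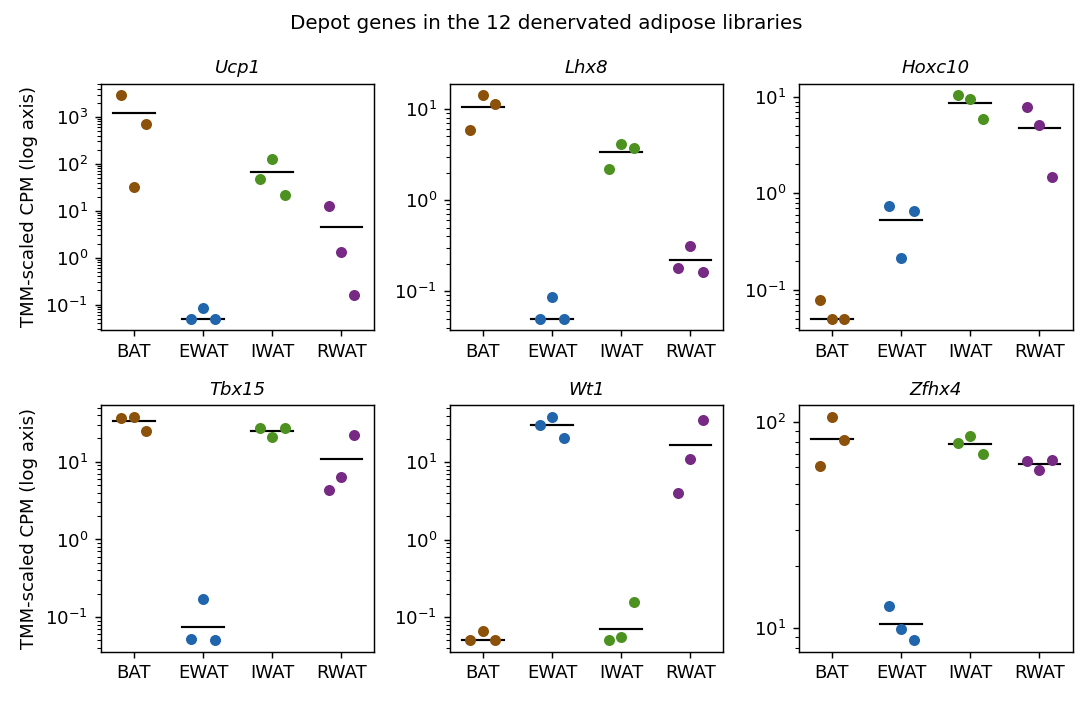
TMM-scaled CPM on a log axis of Ucp1, Lhx8, Hoxc10, Tbx15, Wt1 and Zfhx4 by depot; points are libraries, lines are means, and values under 0.05 CPM are drawn at 0.05. All 3 BAT libraries lie above all 9 white libraries for Lhx8, and Ucp1 spans 32.2 to 2962 CPM within BAT.

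Gene lists were tested with camera. Of 19 thermogenic and brown adipocyte genes, 4 rose and 15 did not pass; adjusted over the list alone, 19 rose, with a median log2 fold change of 3.83 (adjusted p = 1.73e-16, and adjusted p = 0.223 with an estimated correlation). In BAT replicate 2 the mean log2 CPM of this list was 4.41, under the 4.46 and 4.88 of IWAT replicates 1 and 2. For this list and the others called here whose alternatives were run, the estimated correlation gave the highest adjusted p among up to 21 alternatives, except where another value is named. Of 8 brown lineage developmental genes, 2 rose over all genes and 5 adjusted over the list alone, with a median of 1.73 (adjusted p = 3.86e-05, and adjusted p = 0.0572 with an estimated correlation). None of the 49 nuclear-encoded oxidative phosphorylation genes passed over all genes, where 49 rose adjusted over the list alone, with a median of 1.63 (adjusted p = 9.51e-24, and adjusted p = 0.26 with an estimated correlation). Atp5b, of ATP synthase, held 2950 ± 2244 CPM in BAT and 567 ± 43.3 in EWAT. The 13 mitochondrially encoded mRNAs gave 0 over all genes and 13 higher adjusted over the list alone, with a median of 1.56 (adjusted p = 1.37e-08, and adjusted p = 0.26 with an estimated correlation). Of 22 fatty acid oxidation genes, 0 passed over all genes and 19 rose adjusted over the list alone, with a median of 1.78 (adjusted p = 3.4e-11, and adjusted p = 0.26 with an estimated correlation). The BAT libraries overlapped those of IWAT in these 3 lists. Mean log2 CPM in BAT replicates 1 to 3 was 8.98, 7.44 and 7.29 for oxidative phosphorylation, against 7.87 and 7.46 in IWAT replicates 1 and 2. For mitochondrial mRNAs it was 11.36, 10.32 and 10.32 against 10.54 in IWAT replicate 1, and for fatty acid oxidation 9.33, 7.73 and 7.72 against 8.09 in IWAT replicate 1. The 20 de novo lipogenesis genes had a median of 1.83 with 0 members called either over all genes or adjusted over the list alone (adjusted p = 1.66e-06, and adjusted p = 0.351 with an estimated correlation). With 1 surrogate variable, chosen after seeing the data and tied to depot and to this list as given below, the median was 0.22 (adjusted p = 0.265). Beside it, the 18 macrophage markers had a median of −0.966 (adjusted p = 6.36e-05, and adjusted p = 0.351 with an estimated correlation). The 18 lipolysis and lipid droplet genes had a median of 1.01, with 1 member higher adjusted over the list alone and 0 over all genes (adjusted p = 3.56e-05, and adjusted p = 0.351 with an estimated correlation). With the surrogate variable the median was −0.122 (adjusted p = 0.357). Of 8 adrenergic receptor genes, 0 passed over all genes and 4 rose adjusted over the list alone, with a median of 1.12 (adjusted p = 0.00159, and adjusted p = 0.244 with an estimated correlation). With genes under the floor set to it, the medians of the thermogenic and brown lineage lists were again 3.83 and 1.73.

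White adipocyte markers did not pass (adjusted p = 0.464 for 14 genes), nor did the 17 adipokine genes (median 0.207, adjusted p = 0.124). With library sizes alone the adipokine median was −0.258 (adjusted p = 0.0159), in a range of 0.0159 to 0.351 over 21 alternatives. That scaling lowered the median of all genes as well, as given below, and the adipokine median stayed above it. With the surrogate variable, under the limit given below, the median of the white markers was −1.03 (adjusted p = 6.21e-09), in a range of 6.21e-09 to 0.93 over 21 alternatives. The 26 Hox genes split, with 5 higher and 4 lower adjusted over the list alone and 1 lower over all genes (adjusted p = 0.812). The 11 creatine and calcium cycling genes had a median of 0.277 (adjusted p = 0.0837), in a range of 0.00424 without RWAT replicate 3 to 0.434 over 21 alternatives. With library sizes alone their median was −0.187 (adjusted p = 0.0159), again above the lowered median of all genes. Their mean log2 CPM was 5.77, 4.96 and 4.63 in BAT replicates 1 to 3 and 5.25 in RWAT replicate 3. In the other libraries it was 2.53 to 3.68. The same BAT and RWAT libraries were high in muscle markers, so a difference of brown fat in this list cannot be told apart from muscle. Skeletal muscle markers moved with the BAT libraries and with RWAT replicate 3. Their summed level was 23680, 16740 and 2801 CPM in BAT replicates 1 to 3 and 19140 CPM in RWAT replicate 3, against 28.4 to 95.6 CPM in the other 8 libraries. All 18 muscle markers were higher in BAT adjusted over the list alone and 0 over all genes, with a median of 7.22, or 7.03 with genes at the floor (adjusted p = 1.44e-19, and adjusted p = 0.236 with an estimated correlation). Ttn, the titin gene of muscle, held 4353 ± 3365 CPM in BAT and 9.66 ± 1.65 in EWAT (log2 6.19, adjusted p = 0.0857). With 1 library left out, edgeR called it without RWAT replicates 1 or 3 (adjusted p = 0.0461 and 0.000219), in a range of 7.91e-06 to 0.493 over 24 alternatives.

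In all, 19 of 19154 genes were called between BAT and white fat, 17 higher and 2 lower, while 3476 had an unadjusted p under 0.05 where chance alone would give 958. Leaving out 1 library moved this count to 2, 30 and 9 for BAT replicates 1 to 3, to 2, 2 and 2 for EWAT, to 1, 4 and 2 for IWAT and to 263, 6 and 257 for RWAT. DESeq2 and the fit with the replicate number as a block called many more genes, and limma-voom fewer, as given below. Camera called 21 of 30 lists, 14 of them higher in BAT, where an estimated correlation called 0 and fry 12. Without TMM the median of all genes moved from −0.0662 to −0.464 and 8 genes were higher and 3 lower. Ucp1, Elovl3, Cox7a1 and Cpn2 were no longer called without BAT replicates 1 or 3, any EWAT or IWAT library or RWAT replicate 2 (highest adjusted p = 0.189, 0.404, 0.284 and 0.284). Slc27a2 was not called without BAT replicate 1, any EWAT library, IWAT replicates 1 or 3 or RWAT replicate 2 (highest adjusted p = 0.15). Traf4 was not called without BAT replicates 1 or 2, and Hoxc10 without any BAT library, nor either of them without any EWAT or IWAT library or RWAT replicate 2 (highest adjusted p = 0.151 and 0.232). Over all 24 alternatives, calls were lost in 10 for Slc27a2, 12 for Ucp1, 15 for Elovl3 and 13 each for Cox7a1, Cpn2, Traf4 and Hoxc10. Adjusted p reached 0.164 for Slc27a2 with limma-voom and 0.251 for Traf4 with 1 surrogate variable.

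Between the subcutaneous and the intra-abdominal white depots, developmental genes and mesothelial markers differed between IWAT and the mean of EWAT and RWAT. Against RWAT alone, edgeR called 0 genes, with 847 at an unadjusted p under 0.05 where chance alone would give 958; DESeq2 called 163 and limma-voom 0. Tbx15 (chromosome 3, 99240381 to 99354259), a T-box gene of subcutaneous preadipocytes, rose in IWAT by a log2 fold change of 4.70 (SE 0.56, adjusted p = 0.00992). It held 25 ± 3.39 CPM in IWAT (n = 3), 10.9 ± 9.61 in RWAT and 0.0747 ± 0.0877 in EWAT, under the floor. Shox2, a homeobox gene of subcutaneous fat, rose by 5.10 (SE 0.56, adjusted p = 0.00673) to 20 ± 7.38 CPM, against 0.286 ± 0.205 in EWAT and 1.14 ± 0.808 in RWAT. Mmp3, a matrix metalloproteinase, rose by 3.71 (SE 0.31, adjusted p = 0.00344) to 59.9 ± 14.4 CPM, against 1.07 ± 0.107 in EWAT and 19.3 ± 10.3 in RWAT. The zinc finger homeobox gene Zfhx4 had a log2 fold change of 1.61 (SE 0.18, adjusted p = 0.00673), with 77.8 ± 7.72 CPM in IWAT, 62.6 ± 4 in RWAT and 10.4 ± 2.07 in EWAT, so that the low depot was EWAT. Mup10, of the major urinary protein family, rose by 10.07 (SE 1.11, adjusted p = 0.00673) to 1290 ± 752 CPM, against 0.0856 ± 0.148 in EWAT, under the floor, and 14.4 ± 18.6 in RWAT. Mup14 rose by 9.60 (SE 0.92, adjusted p = 0.00344) and Mup9 by 8.78 (SE 1.11, adjusted p = 0.0139). The deposited uncertainty of these 3 counts was 1.07%, 2.09% and 2.08%, so levels are firmer for the family, whose 48 genes summed to 2790 ± 1760 CPM in IWAT, 459.4 ± 121 in BAT, 23.46 ± 27.3 in RWAT and 1.612 ± 1.22 in EWAT. Wt1 (chromosome 2, 105126529 to 105173616), a transcription factor of mesothelium and visceral fat, changed by −8.18 in IWAT (SE 1.03, adjusted p = 0.0139). It held 29.8 ± 9.1 CPM in EWAT, 16.6 ± 16.1 in RWAT and 0.0707 ± 0.0795 in IWAT, under the floor. Bnc1, Upk1b and Upk3b, all expressed in mesothelium, were under the floor in IWAT too and had adjusted p = 0.0135, 0.0228 and 0.0287; their EWAT levels were 11.9 ± 4.13, 18.8 ± 9.42 and 31.2 ± 19.2 CPM.

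Ucp1 held 66.3 ± 56.5 CPM in IWAT, above its mean in EWAT and RWAT, and was not called (log2 7.05, adjusted p = 0.131), and Cidea did not pass either (log2 4.38, adjusted p = 0.392). Tmem26, a beige adipocyte marker, held 6.57 ± 3.2 CPM in IWAT and 6.46 ± 4.59 in EWAT (log2 0.01, adjusted p = 0.999). Hoxc10 (log2 2.44, adjusted p = 0.177), Lep (log2 0.84, adjusted p = 0.713) and Adrb3 (log2 1.17, adjusted p = 0.579) did not pass. DESeq2 called Ucp1 (adjusted p = 4.79e-06) and Hoxc10 (adjusted p = 0.00383), and edgeR called Ucp1 without RWAT replicate 1 (adjusted p = 0.0463). Voom with quality weights, chosen after seeing the data, called Ucp1, Cidea, Hoxc10, Lep and Adrb3 (adjusted p = 0.00885, 0.00226, 0.000616, 0.0253 and 0.000904). The highest adjusted p over 25 alternatives was 0.663, 1, 0.829, 1 and 1 for these genes.

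Of 12 subcutaneous developmental genes, 3 rose in IWAT, Tbx15 and Shox2 among them, and 9 did not pass, and 7 rose adjusted over the list alone, with a median log2 fold change of 2.20 (adjusted p = 5.73e-10, and adjusted p = 0.0282 with an estimated correlation). Of 13 mesothelial markers, 4 fell (Upk3b, Upk1b, Wt1 and Bnc1), and 12 fell adjusted over the list alone, with a median of −6.15, or −5.59 with genes at the floor (adjusted p = 4.68e-24, and adjusted p = 0.0287 with an estimated correlation). Of 11 visceral developmental genes, 2 fell, Wt1 and Bnc1, which are also mesothelial markers, and 6 fell adjusted over the list alone (median −1.28, adjusted p = 1.8e-06, and adjusted p = 0.116 with an estimated correlation). The thermogenic list had 0 of 19 members called over all genes and 13 higher adjusted over the list alone, with a median of 2.32 (adjusted p = 6.95e-12, and adjusted p = 0.212 with an estimated correlation). The 11 beige adipocyte markers had a median of 0.841 with 0 members called over all genes or adjusted over the list alone (adjusted p = 0.0117, and adjusted p = 0.116 with an estimated correlation). The 20 de novo lipogenesis genes also had 0 members called in both ways, with a median of 1.87 (adjusted p = 6.46e-06, and adjusted p = 0.467 with an estimated correlation), beside macrophage markers with a median of −0.509 (adjusted p = 0.0204, and adjusted p = 0.658 with an estimated correlation). The 18 skeletal muscle markers were lower in IWAT, with a median of −3.73 and 0 members called in both ways (adjusted p = 0.00376, and adjusted p = 0.658 with an estimated correlation), beside their sum of 19140 CPM in RWAT replicate 3. The 26 Hox genes (adjusted p = 0.192), the 15 B cell markers (adjusted p = 0.27), the 16 T and NK cell markers (adjusted p = 0.765) and the 8 keratinocyte and mammary epithelial markers (adjusted p = 0.124) did not pass. Hox genes were called without EWAT replicate 1 (adjusted p = 0.0252), B cell markers without IWAT replicate 2 (adjusted p = 0.0172) and T and NK cell markers with the surrogate variable (adjusted p = 0.00112). These were the lowest of 21 alternatives that ranged up to 0.838, 0.667 and 0.945. The 22 extracellular matrix genes had a median of −0.108 (adjusted p = 0.826), and 0.706 with the surrogate variable (adjusted p = 4.7e-07), in a range of 4.7e-07 to 0.99 over 21 alternatives. With genes under the floor set to it, the medians of the subcutaneous, visceral and thermogenic lists were 2.21, −1.28 and 2.33.

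In all, 27 genes were called between IWAT and the intra-abdominal depots, 21 higher and 6 lower, with 2207 at an unadjusted p under 0.05, and 18 of 30 lists, 14 of them higher. Among genes chosen after their values were seen, Mup1, Mup2, Mup11, Mup16 and Mup-ps17 were also higher and Rps16 lower. The calls within the Mup family may not be separate findings. With an estimated correlation 3 lists were called, the subcutaneous developmental, mesothelial and brown lineage ones, and 5 with fry. The count was 14 without BAT replicate 2, 13 and 14 without EWAT replicates 2 and 3, 6, 7 and 41 without IWAT replicates 1 to 3, and 139 without RWAT replicate 1. Without TMM the median of all genes moved from −0.0494 to −0.287. Mmp3, Mup10 and Mup14 were called whichever library was left out. Shox2 was not called without IWAT replicate 1 (adjusted p = 0.0528). Tbx15, Zfhx4 and Bnc1 were not called without IWAT replicates 1 or 2 (highest adjusted p = 0.058, 0.0657 and 0.148), nor was Zfhx4 without TMM (adjusted p = 0.101, the highest of 25 alternatives from 4.75e-14). Wt1 was not called without BAT replicate 2 or IWAT replicates 1 or 2 (highest adjusted p = 0.148), nor with limma-voom (adjusted p = 0.212, the highest of 25 alternatives from 5.18e-14). Upk1b was not called without BAT replicates 1 or 2, EWAT replicates 2 or 3 or any IWAT library, and Upk3b without any EWAT or IWAT library (highest adjusted p = 0.185 and 0.272). Mup9 was not called without EWAT replicates 1 or 2 or IWAT replicates 1 or 2 (highest adjusted p = 0.073).

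Between EWAT and RWAT, both intra-abdominal, the genes called included developmental genes, the matrix metalloproteinase gene Mmp3, and Rps16 with its copy. Zfhx4 (chromosome 3, 5218526 to 5415857) was lower in EWAT, with 10.4 ± 2.07 CPM (n = 3) against 62.6 ± 4 in RWAT (log2 −2.59, SE 0.23, adjusted p = 0.00347). Mmp3 held 1.07 ± 0.107 CPM in EWAT and 19.3 ± 10.3 in RWAT (log2 −4.16, SE 0.42, adjusted p = 0.00607). Rps16 (chromosome 7, 28350652 to 28353155), of the small ribosomal subunit, held 86.4 ± 8.84 CPM in EWAT and 22.2 ± 4.51 in RWAT (log2 1.96, SE 0.22, adjusted p = 0.0122). Rps16-ps2 (chromosome 5, 129128077 to 129128517), its processed copy, held 97.9 ± 5.74 CPM in EWAT and 15.8 ± 4.02 in RWAT (log2 2.63, SE 0.24, adjusted p = 0.00347). The deposited uncertainty of these counts was 2.61% for Rps16 and 2.47% for Rps16-ps2. Among genes chosen after their values were seen, Tbx15 fell in EWAT (log2 −6.99, adjusted p = 0.02) and Bspry rose (log2 4.84, adjusted p = 0.0375). Gm12918, chosen in the same way, was listed at 0 in all IWAT and RWAT libraries, so that its fitted log2 fold change of 13.12 (adjusted p = 0.0288) is no bound. Rps16, Rps16-ps2 and Gm12918 also set the BAT libraries, with those of EWAT, apart from IWAT and RWAT. For them a processing difference between these sets of libraries cannot be told apart from depot.

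**Figure D3:**
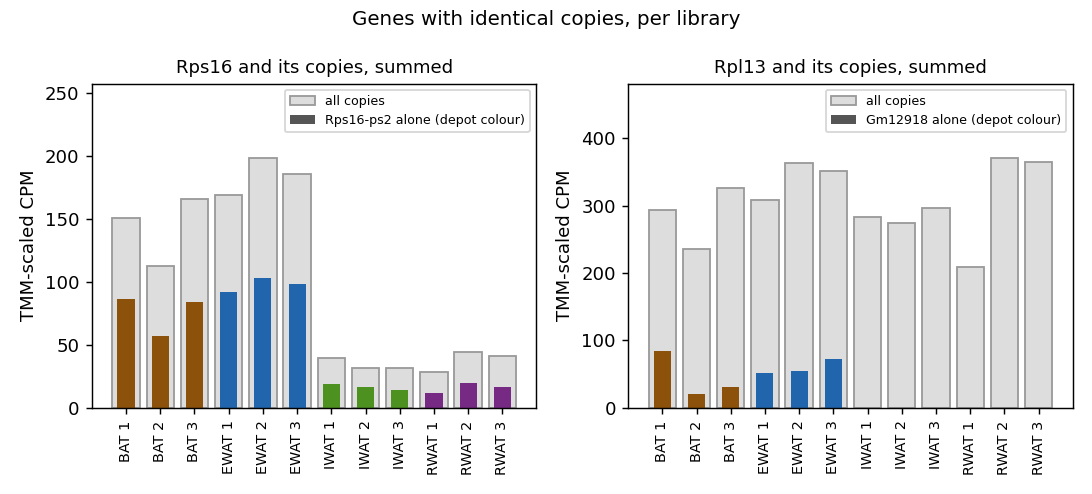
TMM-scaled CPM per library of the Rps16 family sum and Rps16-ps2, and of the Rpl13 family sum and its copy Gm12918; bars start at 0. The Rps16 family averaged 163.8 CPM over the 6 BAT and EWAT libraries and 36.14 over the 6 IWAT and RWAT libraries, where the family of Gm12918 averaged 313.2 and 299.5.

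Wt1 held 29.8 ± 9.1 CPM in EWAT and 16.6 ± 16.1 in RWAT (log2 0.85, adjusted p = 0.79). Ucp1 held 0.0452 ± 0.043 CPM in EWAT, under the floor, and 4.62 ± 6.75 in RWAT (adjusted p = 0.359). Adgre1, the macrophage marker F4/80, held 424 ± 60.5 CPM in EWAT and 218 ± 136 in RWAT (log2 0.96, adjusted p = 0.796). Lep (adjusted p = 0.851), Adrb3 (log2 −1.15, adjusted p = 0.808) and Hoxc10 (log2 −3.17, adjusted p = 0.168) did not pass. DESeq2 called Ucp1 (adjusted p = 0.00363) and Hoxc10 (adjusted p = 0.00107), the lowest of 24 and 25 alternatives, which ranged up to 0.925 and 0.588.

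Of the 26 Hox genes, 18 had a negative log2 fold change and 8 a positive one, with a median of −0.527. Adjusted over the list alone 2 were lower, and 0 over all genes (adjusted p = 9.15e-05, and adjusted p = 0.468 with an estimated correlation). Of the 15 B cell markers, 13 had a positive log2 fold change and 2 a negative one, with a median of 1.26 and 0 members called in both ways (adjusted p = 5.79e-06, and adjusted p = 0.468 with an estimated correlation). The 18 macrophage markers had a median of 0.927 and 0 members called in both ways (adjusted p = 0.00074, and adjusted p = 0.649 with an estimated correlation), and were not called without EWAT replicate 1 (adjusted p = 0.0659) or RWAT replicate 1 (adjusted p = 0.292). The 19 thermogenic genes had a median of −1.42, or −1.32 with genes at the floor, with 1 lower adjusted over the list alone and 0 over all genes (adjusted p = 0.000253, and adjusted p = 0.564 with an estimated correlation). The 11 visceral developmental genes had a median of 0.541 with 0 members called in both ways (adjusted p = 0.00923, and adjusted p = 0.512 with an estimated correlation). Their call was lost without BAT replicate 3 (adjusted p = 0.0517), EWAT replicate 1 (0.295), RWAT replicate 1 (0.214) or RWAT replicate 2 (0.108). Mesothelial markers had a median of 0.489 (adjusted p = 0.0531), and of 1.45 without RWAT replicate 3 (adjusted p = 5.31e-05), in a range of 5.31e-05 to 0.886 over 21 alternatives. De novo lipogenesis genes had a median of −1.75 (adjusted p = 0.113), and of 0.488 without RWAT replicate 1 (adjusted p = 0.254), in a range of 0.00187 to 0.828 over 21 alternatives. Inflammatory cytokine genes did not pass (adjusted p = 0.771), nor did extracellular matrix genes (median −0.605, adjusted p = 0.252), except without RWAT replicate 1 (median −1.10, adjusted p = 0.000123), in a range of 0.000123 to 0.869 over 21 alternatives. None of the 18 epididymis and testis markers and 3 of the 16 kidney and adrenal markers had enough counts to be tested. Of the latter, Mc2r, the receptor of corticotropin, held 4.09 ± 1.3 CPM in EWAT and 6.79 ± 7.52 in RWAT (adjusted p = 0.845). It held 7.23 ± 3.38 CPM in BAT and 8.05 ± 5.48 in IWAT too, so its level did not set RWAT apart.

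In all, 8 genes were called between EWAT and RWAT, 4 higher and 4 lower, with 1732 at an unadjusted p under 0.05, and 13 of 30 lists, 4 of them higher, where an estimated correlation called 0 and fry 2. The count was 804 without EWAT replicate 1 and 0 without EWAT replicate 2, where 1016 had an unadjusted p under 0.05. Zfhx4, Mmp3, Rps16 and Rps16-ps2 were not called without EWAT replicate 2 (adjusted p = 0.0523 to 0.0643), nor was Rps16 without RWAT replicates 2 or 3 (adjusted p up to 0.0643). Tbx15 was not called without BAT or IWAT replicates 1 or 2 or EWAT replicates 2 or 3, and Gm12918 without BAT replicate 3, EWAT replicates 2 or 3 or any RWAT library (highest adjusted p = 0.0643 and 0.145). Bspry was not called without EWAT replicate 2 or any BAT, IWAT or RWAT library (highest adjusted p = 0.217). A fit of only these depots called 0 genes, with 1443 at an unadjusted p under 0.05, and gave adjusted p = 0.0548 for Zfhx4, 0.239 for Mmp3, 0.11 for Rps16-ps2 and 0.22 for Rps16, the highest of 24 or 25 alternatives for each. The lowest for each were 1.61e-25, 8.05e-18, 3.07e-20 and 4.31e-13. With library sizes alone, 2 genes were higher and 4 lower, and the median of all genes moved from −0.0382 to 0.0483.

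Between single depots, 150 genes were called between BAT and EWAT, 78 higher in BAT and 72 lower; with library sizes alone it was 62 and 171. Leaving out 1 library gave 8, 6 and 1996 genes for BAT replicates 1 to 3, 1159, 6 and 24 for EWAT, 10, 16 and 101 for IWAT, and 1420, 131 and 372 for RWAT. IWAT and EWAT differed in 66 genes, 38 higher in IWAT and 28 lower. Without BAT replicates 1 to 3 that count was 20, 24 and 35, without EWAT 1097, 8 and 29, without IWAT 11, 7 and 57, and without RWAT 115, 73 and 89. BAT and RWAT differed in 11 genes, 6 higher in BAT and 5 lower, or 3 and 7 with library sizes alone. That count was 2, 1 and 0 without BAT replicates 1 to 3, 2, 2 and 3 without EWAT, 2, 0 and 4 without IWAT, and 1, 3 and 45 without RWAT. At the values of 0, edgeR had 5128 genes at an unadjusted p under 0.05 without BAT replicate 3 and 2325 without IWAT replicate 2.

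Between BAT and IWAT edgeR called 2 genes, both chosen after their values were seen: Rps16-ps2 (log2 2.19, SE 0.23, adjusted p = 0.0332) and Rps16 (log2 1.95, SE 0.22, adjusted p = 0.0332). Both also set EWAT, with BAT, apart from IWAT and RWAT, so a processing difference cannot be told apart from depot here. With all libraries, 737 had an unadjusted p under 0.05 where chance alone would give 958. So few calls do not show that BAT and IWAT are otherwise alike. Skeletal muscle markers, for instance, summed to 23680, 16740 and 2801 CPM in BAT replicates 1 to 3. In IWAT they summed to 64.92, 59.87 and 33.37 CPM. Without TMM 1 gene was higher and 1 lower. The count was 1 without BAT replicate 1, BAT replicate 2 or RWAT replicate 2, 97 without RWAT replicate 3, and 0 without BAT replicate 3 or any EWAT or IWAT library, where 511 to 2252 genes had an unadjusted p under 0.05. Between IWAT and RWAT edgeR called 0 genes, with 847 at an unadjusted p under 0.05, fewer than the 958 of chance alone. This does not show that the 2 depots are alike. Mean log2 CPM of the mesothelial markers was −1.435, −0.7075 and −1.102 in IWAT replicates 1 to 3. In RWAT it was 2.715, 2.628 and 4.716. DESeq2 called 163 genes between these depots, limma-voom 0 and voom with quality weights 4013, and edgeR called 3 without IWAT replicate 3. Bspry, chosen after its values were seen, was the 1 gene enriched in EWAT against each other depot, with 10.8 ± 8.25 CPM there against 0.598 ± 0.131 in BAT, 0.566 ± 0.232 in IWAT and 0.372 ± 0.11 in RWAT. Beside it, the keratinocyte and mammary epithelial markers summed to 172.1, 32.85 and 18.15 CPM in EWAT replicates 1 to 3 and to 12.51, 9.009 and 46.11 in RWAT. Between these depots the list had a median of 0.199, with 2 of 8 members higher adjusted over the list alone and 0 over all genes (adjusted p = 0.0532, and adjusted p = 0.512 with an estimated correlation). Leaving out 1 library gave 0 to 655 genes enriched in EWAT, with 655 without EWAT replicate 1. By edgeR 0 genes were enriched in BAT, IWAT or RWAT, against 79, 13 and 11 at unadjusted p under 0.05. There, 8 simulations with no change gave 6 to 23, 5 to 15 and 8 to 15. They drew genes independently, so these ranges may be too narrow for genes that vary together. DESeq2 gave 11, 0 and 1 and limma-voom 0, 0 and 0. Without RWAT replicate 3, edgeR gave 33 genes enriched in BAT.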

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

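The surrogate variable, the quality weights and the removal of uncertain counts were tests chosen only after the results were seen. The surrogate variable was estimated from the same counts and was not independent of depot. It was 0.521, 0.349 and −0.0573 in BAT replicates 1 to 3 and −0.187, −0.177 and −0.294 in EWAT. In RWAT it was 0.215, −0.349 and −0.283, where the lipogenesis list had means of 9.47, 6.06 and 6.28. Its fits therefore cannot decide whether adipocyte lists differ between depots. Scaling by RLE, the stricter filter and the removal of mitochondrial, ribosomal and small RNA genes moved no count by over 1.5 times. Over the other settings the counts of genes moved as follows, and the cause was not tested. DESeq2 called 907 genes for BAT against white, 340 for IWAT against EWAT and RWAT, 788 for EWAT against RWAT, 3434 for BAT against EWAT, 167 for BAT against IWAT, 311 for BAT against RWAT, 1433 for IWAT against EWAT and 163 for IWAT against RWAT, with 11, 373 and 1 genes enriched in BAT, EWAT and RWAT. Limma-voom called 3 for BAT against white, 16 for IWAT against EWAT and RWAT, 19 for BAT against EWAT, 1 for BAT against RWAT and 25 for IWAT against EWAT, with 3 enriched in EWAT. Library sizes alone gave 11 for BAT against white, 233 for BAT against EWAT and 0 enriched in EWAT. Without a filter on counts, BAT against white gave 47 and BAT against IWAT 4. The replicate number as a block gave 649 for BAT against white, 3542 for BAT against EWAT, 0 for BAT against IWAT (942 at an unadjusted p under 0.05), 1 for BAT against RWAT, 123 for IWAT against EWAT and 3 enriched in EWAT. For BAT against white it called Cidea, Ppargc1a, Prdm16, Zic1, Atp5b and Ttn (adjusted p = 0.0473, 0.0457, 0.0457, 0.0187, 0.0487 and 0.0484). Against a 1.5-fold change glmTreat gave 4, 17, 0 (457 unadjusted), 2 and 42 for BAT against white, BAT against EWAT, BAT against IWAT, BAT against RWAT and IWAT against EWAT. A fit of only the depots compared gave 14 for IWAT against EWAT and RWAT, 0 for EWAT against RWAT (1443 unadjusted), 1051 for BAT against EWAT, 0 for BAT against IWAT (556 unadjusted), 0 for BAT against RWAT (1630 unadjusted) and 102 for IWAT against EWAT. Voom with quality weights gave 73 for BAT against white, 9124 for IWAT against EWAT and RWAT, 18 for EWAT against RWAT, 4739 for BAT against EWAT, 85 for BAT against IWAT, 4 for BAT against RWAT, 8702 for IWAT against EWAT and 4013 for IWAT against RWAT, with 1, 4 and 7 enriched in BAT, EWAT and IWAT. Without genes of uncertain count it was 13 for IWAT against EWAT and RWAT, 4 for EWAT against RWAT, 0 for BAT against IWAT (504 unadjusted), 1 for BAT against RWAT and 0 enriched in EWAT. With 1 surrogate variable it was 95 for EWAT against RWAT, 79 for BAT against EWAT, 6 for BAT against IWAT, 157 for IWAT against EWAT and 5 enriched in EWAT. Of the gene lists in the 3 main comparisons, an estimated correlation called 0, 3 and 0, and fry 12, 5 and 2. With the surrogate variable the median of the lipolysis list in BAT against white reversed to −0.122, and that of the extracellular matrix list in IWAT against EWAT and RWAT to 0.706.

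Leaving out each library in turn gave 1 to 263 genes for BAT against white, 6 to 139 for IWAT against EWAT and RWAT, 0 to 804 for EWAT against RWAT, 6 to 1996 for BAT against EWAT, 0 to 97 for BAT against IWAT, 0 to 45 for BAT against RWAT, 7 to 1097 for IWAT against EWAT and 0 to 3 for IWAT against RWAT. Genes enriched were 0 to 33 in BAT, 0 to 655 in EWAT, 0 to 0 in IWAT and 0 to 0 in RWAT, and lists called were 20 to 22, 16 to 22 and 11 to 21. Over the alternatives for named lists, 612 of 692 values kept their direction and side of the threshold, 35 became weaker, 24 stronger, 19 moved and 2 reversed. For named genes together with all called genes of the 3 main comparisons, 1935 of 2470 kept both, 436 became weaker, 42 stronger, 57 moved and 0 reversed. Only values of genes or lists called in the main test can become weaker, so these shares understate how often calls were lost. The samples were not treated as paired by replicate number, whose meaning the labels do not give, since only 10 of 18 pairs of libraries with the same number had deviations from the depot mean that correlated over 0.1 across genes. The 6 pairs of number 1 (0.0235 to 0.629) and the 6 of number 3 (0.0315 to 0.677) were all positive, but only 1 of the 6 of number 2 (−0.347 to 0.122). Of the 12 libraries, 8 correlated best with those of their own number. The data thus hint that libraries with the same number share something, for which only the fit with the block accounts.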

Other observations

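Among the tests below, those on shared copies, exchanged labels, the share of adipocytes, the replicate numbers, the muscle markers of RWAT replicate 3 and a BAT library under its label were chosen only after the result was seen. Of 20 sympathetic neuron and Schwann cell genes, 15 had enough counts to be tested. Th, with 7 counts over the 12 libraries, and Dbh, also of noradrenaline synthesis and named after its 4 counts were seen, did not. The 15 tested genes had a median log2 fold change of −0.158 between BAT and white fat (adjusted p = 0.157). The 10 neurotrophic factor genes had a median of 1.46 in BAT, with 4 higher adjusted over the list alone and 0 over all genes (adjusted p = 0.0229, and adjusted p = 0.244 with an estimated correlation). Mesothelial markers were lower in BAT than in white fat, with 13 of 13 lower adjusted over the list alone, 0 over all genes and a median of −3.95, or −3.66 with genes at the floor (adjusted p = 1.85e-14, and adjusted p = 0.125 with an estimated correlation). Subcutaneous developmental genes rose in BAT, with 8 of 12 higher and 1 lower adjusted over the list alone, 1 higher and 1 lower over all genes, and a median of 1.80, or 1.68 with genes at the floor (adjusted p = 6.2e-05, and adjusted p = 0.125 with an estimated correlation). Brown lineage genes rose in IWAT against EWAT and RWAT, with 1 of 8 called, Lhx8, and 3 adjusted over the list alone (median 0.997, adjusted p = 9.43e-05, and adjusted p = 0.0287 with an estimated correlation).

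Of the immune lists, 3 were lower in BAT than in white fat with 0 members called over all genes, and T and NK cell markers did not pass (adjusted p = 0.108). Macrophage markers had a median of −0.966 with 0 members called adjusted over the list alone (adjusted p = 6.36e-05, and adjusted p = 0.351 with an estimated correlation). The BAT libraries overlapped the white ones. Mean log2 CPM of macrophage markers was 5.19, 5.63 and 7.72 in BAT replicates 1 to 3, against 6.16, 7.08 and 7.92 in IWAT. B cell markers had a median of −1.16 with 2 lower adjusted over the list alone (adjusted p = 5.05e-05, and adjusted p = 0.26 with an estimated correlation). Inflammatory cytokine genes had a median of −1.26 with 0 called adjusted over the list alone (adjusted p = 0.000401, and adjusted p = 0.351 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.965 in BAT, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00159, and adjusted p = 0.351 with an estimated correlation); Aldoa, a glycolytic enzyme abundant in muscle, chosen after its values were seen, had a log2 fold change of 1.74 (adjusted p = 0.155), beside the muscle markers of these libraries. Circadian clock genes had a median of 0.573 with 0 called adjusted over the list alone (adjusted p = 0.00782, and adjusted p = 0.351 with an estimated correlation). Stromal progenitor markers had a median of 0.991 in IWAT against EWAT and RWAT, with 5 of 13 higher adjusted over the list alone and 0 over all genes (adjusted p = 9.68e-05, and adjusted p = 0.344 with an estimated correlation). Between EWAT and RWAT, stromal progenitor markers had a median of −0.89 (adjusted p = 1.72e-05, and adjusted p = 0.468 with an estimated correlation) and endothelial markers of −0.512 (adjusted p = 0.001, and adjusted p = 0.512 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. Muscle markers were lower in EWAT than in RWAT with a median of −7.76, or −7.77 with genes at the floor, and 18 of 18 lower adjusted over the list alone (adjusted p = 1.02e-09, and adjusted p = 0.512 with an estimated correlation), beside the sum of 19140 CPM in RWAT replicate 3.

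Rps16, Rps16-ps2 and Gm12918 differed between the 6 BAT and EWAT libraries and the 6 IWAT and RWAT libraries, as did 5S ribosomal RNA, with 3.05 to 9.68 CPM in the first set and 13.1 to 25.1 in the second, so that a processing difference between these sets, not named in the labels, cannot be told apart from depot. Of genes with mostly shared sequence, 10 of 890 were at p under 0.001 between the sets, against 28 of 17886 others. The odds ratio was 7.25 (95% interval 3.13 to 15.4), where the other groupings of depots in pairs gave 1.17 and 0.477. But the grouping was picked because of Rps16, Rps16-ps2 and Gm12918. Rps16-ps2 and Gm12918 share 100% of their sequence with another gene and were not left out. The ratio is thus partly fixed in advance. Reads assigned differently between copies may add to the pattern, which this ratio cannot decide. For Gm12918 the summed family differed by a log2 of 0.076 (SD 0.268), at 313.2 and 299.5 CPM, as reads moved among its copies would give. For Rps16 the family sum itself differed by 2.18 (SD 0.272), 163.8 ± 29.9 against 36.14 ± 6.41 CPM, which argues against reads moved among annotated copies as its cause. A difference between depots in Rps16 stays open and untested.

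Within depots, libraries lay along 1 axis from adipocyte genes to macrophage and matrix genes, which held 46.4% of the within-depot variance. The axis held 45.8% after each library's GC and length trend was removed, which argues against these trends as its cause, and exchanged labels of IWAT replicate 3 and RWAT replicate 1 were argued against by their mesothelial markers, nearer to the labelled depot by a log2 of at least 2.83. A lower share of adipocytes alone would raise endothelial markers with macrophage markers, but their slope ratio was −0.146 (−0.229 to −0.0771 with 1 library left out). Scores were negative in replicate 1 and positive in replicate 3 of all 4 depots, and 73.6% of their variance lay between replicate numbers (exact permutation p = 0.0139 over the 1296 ways to reassign numbers within depots). Something shared by libraries with the same number, such as an animal, a day or a dissection, may thus contribute, as may more macrophages in some samples.

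Skeletal muscle transcripts were high in BAT and in RWAT replicate 3, where the 18 markers took 2.25% of the counts, against 1.46%, 1.46% and 0.272% in BAT replicates 1 to 3. In RWAT replicate 3, 100% of the markers were above both other RWAT libraries, by a median log2 of 8.12, and Ttn held 7339 CPM. These values describe the high level and do not test its source. Adjoining muscle in the sample may be that source. A BAT library under that label was argued against, since brown lineage genes were nearer to the other RWAT libraries than to BAT by a log2 of 1.93. Across the 18 markers, the BAT libraries correlated with RWAT replicate 3 at 0.931 or more, so muscle may be the source in BAT as well. Expression of muscle genes by brown adipocytes stays open.

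The samples were regrouped at random in 100 splits, the real one included and replicate numbers ignored. For the 19 genes of BAT against white, 4 of 100 splits were as large (highest other 2113). For its 21 lists it was 3 of 100 (highest other 21). These shares lie under 0.05, but the splits take the libraries as exchangeable. Libraries with the same number may share something, so chance is not excluded. Nor could chance be excluded for the 27 genes of IWAT against EWAT and RWAT (8 of 100, highest other 5049) or its 18 lists (12 of 100, highest other 22). The split with 5049 genes exchanges IWAT replicate 3 and RWAT replicate 1, and counts that high point to a structure of the samples, as does 2113. For the 1 gene enriched in EWAT, 1 of 100 splits was as large (highest other 0), with the same limit. This gene, Bspry, chosen after its values were seen, lost its call against RWAT in 10 of the 12 fits with 1 library left out. For the 0 genes enriched in BAT, IWAT and RWAT the splits decide nothing, since 100 of 100 must reach 0 (highest other 5, 1 and 0). For pairs of depots the 10 splits are too few for a share under 0.05. There EWAT against RWAT gave 8 genes (1 split as large; highest other 0) and 13 lists (6; 17), BAT against EWAT 150 (1; 1), BAT against IWAT 2 (2; 4), BAT against RWAT 11 (2; 3566), and IWAT against EWAT 66 (1; 0). For the 0 genes of IWAT against RWAT all 10 splits must reach 0 (highest other 2943). The high other values of 3566 and 2943 point to a structure of the samples too.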
